A study of Arabidopsis thaliana with 4 samples.

How the data were processed

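The series measured messenger RNA of Arabidopsis thaliana seedlings (accession Col-0, wild type), grown for 4 days in the dark and then kept dark or given 4 h of light. Per the labels' protocols, total RNA was extracted by the Pine Tree method and polysomal RNA with phenol and chloroform, mRNA was purified with an Oligotex kit, and libraries followed standard Illumina protocols. The 4 groups are total RNA dark, total RNA light, polysomal RNA dark and polysomal RNA light, with 1 library each, so fraction and extraction method differ together. A microarray experiment named in the series' design text was not used here. The genome build in the submitters' processing notes is TAIR10, and the aligner, the counting program and the use of strand are not given in the sources used here.

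One deposited table lists 33602 gene entries with, per the file headers, gene length, read counts and RPKM of each library and a log2 ratio of light over dark by the authors. The read counts of total mRNA are whole numbers, none of them 0, so a count of 1 may stand for 0 there. The deposited polysomal reads are estimated counts: 19.7% of values in the dark and 20.4% in the light are not whole, which reads shared between genes would give, and 3977 (22.5%) of the tested genes have such a value. RPKM values were made by the authors per kilobase and scaled to library size, per the file headers. In total mRNA they follow from the deposited reads and length, and in polysomal mRNA the length behind them is shorter for short genes (95.8% of the deposited length at 0.5 to 0.75 kb, set against genes over 3 kb). Tested on the values, a gene is listed for a fraction only when its RPKM reaches 0.5 in 1 of the 2 libraries, and 0 reads in polysomal mRNA are written as an RPKM of 0.01, in 34 genes in the dark and 43 in the light. The reads listed per library run from 61006149 to 91087442. Total mRNA lists 19632 genes and polysomal mRNA 19093, of which 18584 have all 4 values. Another 1048 genes with total and 509 with polysomal values only went into no comparison.

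The other deposited tables hold splicing events. Per the file headers, they give for total mRNA the event reads (counts, with a few estimated counts that are not whole), the percent of reads with the event in the dark and in the light, the authors' log2 ratio of these and a p-value of a chi-square test by the authors, not adjusted. A table of polysomal events gives percent values and log2 ratios by the authors without reads, so its depth is unknown. Another list holds the events the authors set as light-regulated, all with a deposited p-value under 0.01 and a ratio of at least 1.5. The header text calls the log2 column of the full event table a ratio of polysomal RPKM, but its values are those of the percents. The authors' p-values equal those of a goodness-of-fit chi-square test that takes the reads of the reference form as exact for 99.6% of the tested events, within 0.05 on the log10 scale. The total of reads behind each percent was recovered from event reads and percent. It came out whole within 0.01 for 100% of retained introns, 96.4% of donor or acceptor events and 36.9% of exon skipping events, and was rounded for the others. The 607 cryptic exon events, whose totals were unclear, were left out of the test. The events reach at least 5 reads and 5% in 1 of the total mRNA libraries.

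Expression was compared as the log2 ratio of (RPKM + 1) among the 17684 genes with a mean of at least 1 RPKM over the 4 libraries, a pseudocount of 1 and no further scaling. Genes at least 2-fold higher or lower were counted in 5 comparisons: light against dark in total mRNA and in polysomal mRNA, polysomal against total mRNA in the dark and in the light, and the difference of the last 2 ratios. With 1 library per group no p-value across genes was computed. Fold values of named genes are ratios of RPKM with exact 95% intervals from the reads (binomial, counting error only, with estimated reads rounded to whole numbers). A gene listed at 0 was set against a floor of 3 reads in its library.

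Lists were fixed before the data were examined, as were the thresholds and the rule for named genes. The 20 lists, 18 of nuclear genes, hold 301 nuclear genes and every gene with a plastid or mitochondrial identifier: LHC antenna, photosystem subunits, Calvin cycle, chlorophyll synthesis, carotenoid synthesis, flavonoid synthesis, light response regulators, photoreceptors and PIFs, circadian clock, etiolated growth and auxin, SR proteins, other splicing regulators, NMD factors (nonsense-mediated mRNA decay), cytosolic ribosomal proteins, storage oil breakdown, heat and handling stress, plastid-encoded and mitochondria-encoded genes, and, as markers of other tissue, seed storage proteins and root markers. For each list the median ratio was placed among 10000 random lists of the same size matched on mean log2 RPKM in 20 bins, and members past 2-fold were counted. Lists outside the central 95% are said to stand apart, with no p-value. Lists with under 5 measured genes have no percentile.

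Named genes are, per comparison, the 10 highest and 10 lowest ratios among genes with a symbol and a mean of at least 10 RPKM, and up to 4 members of each list, the 2 highest and the 2 lowest with a mean of at least 1 RPKM, or any member of lists of up to 12 genes. Where 5 or fewer members of a list passed 2-fold, members outside this rule were named too (PRR9, RVE1, FHY1, PHOT1, F3H and FBA1), as were RCA, SBPASE, RBCS3B, PRK, AT2G28671, AT1G58684 and AT1G59359, all chosen after their values were seen. Named events are those past the rule in 4 lists (SR proteins, other splicing regulators, clock, light response regulators), the 10 largest changes and the 10 lowest p-values.

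Splicing events were tested by Fisher's exact test, two-sided, on event reads against reads of the reference form in the 2 total mRNA libraries, for 20007 events with at least 10 reads in each. In every named retained intron the recovered reads of the reference form are an even number in both libraries, as spliced reads counted 2 times would give. If so, p-values, intervals and the minimum of 10 reads overstate the evidence for retained introns. Benjamini-Hochberg adjustment was applied over these events, and an event counts as changed at an adjusted p of 0.05 or less and a change of at least 10 percentage points. Shares have exact 95% binomial intervals. Genes with a changed event were compared with genes past 2-fold by odds ratio and against random genes matched on expression. Retained introns were placed on the TAIR10.1 reference, which may differ from the build used by the authors: 97.8% had a matching intron there, 12014 in coding sequence, 1149 in the 5' UTR and 321 in the 3' UTR. Of the genes with any value, 98.9% matched a locus of the reference. Coordinates are those of TAIR10.1.

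The comparisons of expression, of lists and of splicing events were tested on simulated data. With reads drawn for 17684 genes with counting noise (Poisson) only, 0 of 17484 unchanged genes passed 2-fold. Variation between plants, extractions and libraries was not simulated, so these values are no error rate of the calls. In total mRNA the rule found 0 of 50 genes changed 1.5-fold, 90% at 3-fold, 94% at 4-fold and 96% at 8-fold, and in polysomal mRNA 82%, 92% and 100% at 3-fold, 4-fold and 8-fold. Of 100 lists of unchanged genes 6 lay outside the central 95%. For splicing, 35.8% of events changed by 15 points were found, 53.7% at 25 points and 81.8% at 40 points, and 2 of 19807 unchanged events.

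Alternatives tried were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 RPKM, centring on the median of genes with at least 5 RPKM, rescaling to the sum over nuclear genes, thresholds of 1.5-fold and 3-fold, event minimums of 5 and 20 reads, 20 points, each gene counted once, list members, events or background genes of at least 5 RPKM, and the overlap at 1.5-fold. Chosen after seeing the data were RPKM recomputed from reads and deposited length, genes with whole polysomal reads, genes that overlap no other gene, removal of the length trend, random lists matched on length as well, cryptic exons with whole totals, and a background of genes with a tested event. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.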

Results

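Messenger RNA was sequenced from 4-day-old etiolated seedlings of wild-type Arabidopsis thaliana (accession Col-0), either kept in the dark or given 4 h of light. In each condition 1 library was made from total RNA and 1 from polysomal RNA, the RNA bound to several ribosomes at once, so the 4 groups hold 1 library each and no difference below has a replicate check. The reads listed per library numbered 64950412 in total dark, 91087442 in total light, 77849944 in polysomal dark and 61006149 in polysomal light. The median gene had 946, 1465, 1029 and 750 reads in that order. The 10 most abundant genes took 5.04% and 4.77% of the reads in total dark and light, and 7.38% and 9.27% in polysomal dark and light. In all, 17684 genes had values in the 4 libraries and a mean of at least 1 RPKM (reads per kilobase of gene, scaled to the size of the library). Ratios are log2 of (RPKM + 1), which understates the change of genes of low abundance, and a gene is said to have risen or fallen when it changed at least 2-fold on that scale. Fold values are ratios of RPKM, and their 95% intervals cover counting error only.

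The first comparison asked which transcripts differ in total mRNA after 4 h of light. Extremes named for each comparison are those on the log2 scale among genes with a symbol and a mean of at least 10 RPKM, and genes outside that limit can lie beyond them. LHCB1.1 (AT1G29920), which encodes a chlorophyll-binding antenna protein, went from 7.54 to 940.6 RPKM, 125-fold (115 to 135). RBCS1B (AT5G38430), a small subunit of Rubisco, rose 78.9-fold (72.3 to 86.3), ELIP1 (AT3G22840), an early light-induced protein, 89.5-fold (74.1 to 109), and SIG5 (AT5G24120), a sigma factor of the plastid RNA polymerase, 78.4-fold (68.5 to 90.2). At the other end, PORA (AT5G54190), the protochlorophyllide reductase of dark-grown seedlings, fell from 109.7 to 2.00 RPKM, a log2 ratio of -5.21, and PIL1 (AT2G46970), a phytochrome-regulated factor of the bHLH family, fell from 22.0 to 0.68 RPKM. On the TAIR10.1 reference LHCB1.1 lies on chromosome 1 (10474656 to 10475969), RBCS1B, SIG5 and PORA on chromosome 5 (15383167 to 15385320, 8157151 to 8160343 and 21990864 to 21992814), ELIP1 on chromosome 3 (8084405 to 8085669) and PIL1 on chromosome 2 (19295431 to 19297858). LHCB1.1 and RBCS1B belong to families of near-identical copies that can share reads. Summed over LHCB1.1, LHCB1.2 and LHCB1.3 the RPKM rose 7.50-fold, and summed over the 4 Rubisco small subunit genes 6.87-fold.

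The lists of photosynthesis genes moved as blocks. All 20 measured antenna (LHC) genes rose, with a median log2 ratio of 2.98, from LHCB4.2 at 1.09 and LHCB4.1 at 1.37 up to LHCB1.4 at 5.56 and LHCB1.1 at 6.78. All 26 photosystem subunits rose as well (median 2.55), led by PSBS at 3.82 and PSBO2 at 3.77, with PSAE2 the lowest at 1.06. Of 16 Calvin cycle genes 15 rose (median 3.24), FBA1, a plastid aldolase, by 5.10, while the triose phosphate isomerase TIM stood at 0.43. Of 25 genes of chlorophyll synthesis 14 rose, among them DVR (3.35) and GUN4 (3.14), 2 fell, PORA and PORB (-1.02), and 9 lay between. Of 11 carotenoid genes 8 rose, led by the phytoene synthase PSY, 5.89-fold (5.66 to 6.12), and ZEP at 2.22 on the log2 scale, and 3 did not pass 2-fold (BCH1 0.75, LYC 0.72, CRTISO 0.71). In flavonoid synthesis 11 of 16 genes rose, including the chalcone synthase CHS, 39.4-fold (34.8 to 44.8), and UGT78D2 at 3.82, and 5 lay between, such as F3'H at -0.14. Among 21 regulators of the light response 18 rose, 2 fell (BBX20 -1.82, BBX21 -1.32) and 1 lay between.

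Genes of growth in the dark went the other way. Of 20 measured genes of the list of etiolated growth and auxin 16 fell and 4 lay between, with a median of -2.21. PIL1 stood at -3.78 and ATHB2, a homeodomain factor of the shade response, at -3.47, against -0.15 for HFR1 and -0.80 for IAA3. Of the photoreceptors and PIFs, PHYA (-1.86), its partner FHL (-2.14) and FHY1 (-1.46) fell, PHOT2 rose (1.77), and 10 of 14 lay between. Storage oil breakdown had 2 genes that fell, the isocitrate lyase ICL (-1.87) and PCK1 (-2.69), and 8 between. In the clock list 4 of 19 genes rose, ELF4 (3.32), LNK1 (2.05), PRR9 (1.87) and RVE1, and 15 lay between, LHY lowest at -0.85. The RNA-binding protein GRP7 fell (-1.57), with the other 9 of the list of other splicing regulators between, GRP8 at -0.79. None of the 20 SR proteins, factors that guide splice site choice, passed 2-fold (SR34a 0.69, SR34 -0.99, median -0.08), nor did any of 31 cytosolic ribosomal proteins (median 0.27; RPS28B 0.75, RPS18C -0.33) or 5 NMD factors (median -0.12; UPF3 -0.43).

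Some lists serve as markers of handling, of organelles or of other tissue. Of 16 genes of heat and handling stress 7 rose with light, HSP70 by 2.72 and HSP90.1 by 2.04, and none fell (median 0.97). Of 68 plastid-encoded genes 7 rose, ATCG00630 by 3.11, and 61 lay between (median 0.33), and of 8 mitochondria-encoded genes 3 rose, ATMG01380 by 1.70, ATMG00030 by 1.49 and ATMG01080 by 1.38. After purification with the Oligotex kit, plastid genes held at most 0.325% and mitochondrial genes at most 0.108% of the listed reads of a library. How fully organelle RNA passed that step was not tested. Organelle ratios, here and below, may therefore not stand for organelle mRNA level or ribosome load. None of 6 measured seed storage genes passed 2-fold (median -0.39; CRA1 -0.99), and only SCR (0.42) and SHR (-0.38) of 8 root markers were measured.

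Over all genes 1888 rose in total mRNA and 1014 fell, with a median log2 ratio of -0.02. Against 10000 random lists of the same size and expression, the medians of the antenna, photosystem, Calvin cycle, chlorophyll, flavonoid, light regulator, heat and plastid lists lay at percentile 100, those of the carotenoid and clock lists at 100.0 and 99.7. Ribosomal proteins lay at 90.9 and mitochondria-encoded genes at 85.8, inside the central 95%, as did photoreceptors at 54.8, NMD factors at 41.8, SR proteins at 39.8, storage oil breakdown at 7.35 and seed storage at 6.23. The list of etiolated growth and auxin lay at percentile 0 and that of other splicing regulators at 1.41. These percentiles describe the 2 libraries and are no test of the conditions. The loci of CHS, GUN4, PSY, PORB, LNK1, PHOT2, BBX20, TIM, LYC, IAA3, RPS18C, PSAE2 and LHCB4.2 overlap another gene on the reference, and the sources used here do not say whether strand was used in counting, so their reads and those of the partner gene may be mixed.

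**Figure D1:**
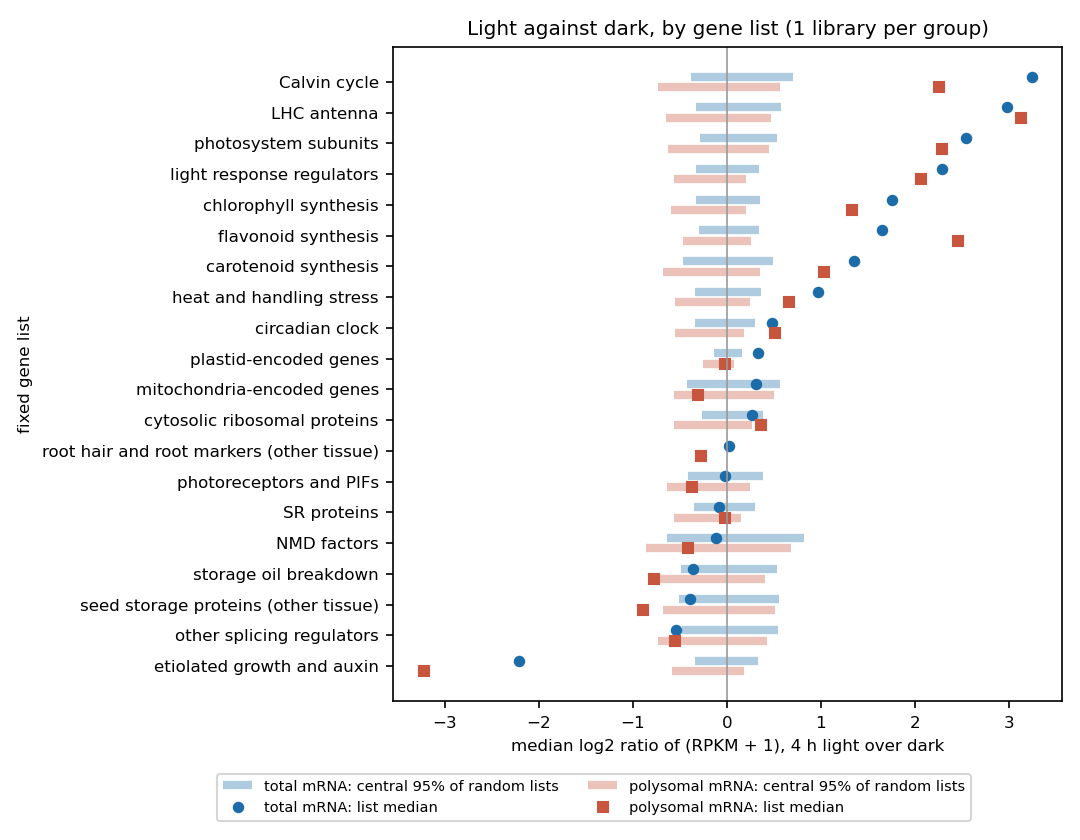
Median log2 ratio of (RPKM + 1), 4 h light over dark, for each of the 20 gene lists in total mRNA (circles) and polysomal mRNA (squares), with bars for the central 95% of 10000 random lists matched on expression. Calvin cycle, antenna and photosystem genes stand highest in total mRNA at 3.24, 2.98 and 2.55, and etiolated growth and auxin lowest in both fractions, at -2.21 and -3.22; the root markers, with 2 genes, have no bar.

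The same comparison in polysomal mRNA asked how the pool of mRNA on ribosomes differs with light. The germin-like gene GER1 (AT1G72610; chromosome 1, 27339114 to 27340044) had the highest log2 ratio among genes with a symbol and a mean of at least 10 RPKM, 6.50, or 109-fold (98.5 to 122), with ELIP1 next at 4.84. F3H, the flavanone hydroxylase, rose 52.9-fold, or 4.56 on the log2 scale, which counts a low dark value less, CHS by 4.00 on the log2 scale and LHCB1.1 18.6-fold (18.3 to 18.9). The summed RPKM of LHCB1.1, LHCB1.2 and LHCB1.3 rose 9.89-fold and that of the 4 Rubisco small subunit genes 3.97-fold. PORA fell furthest among genes with a symbol and reads in both libraries (log2 -6.18), ahead of SNRK2.5 (-5.42), MSRB7 (-5.33), the growth-regulating factor GRF7 (-5.20) and the auxin response repressor IAA6 (-4.76). UBQ6 (AT2G47110; chromosome 2, 19344635 to 19345345), a ubiquitin gene, was listed with 0 polysomal reads in the light and 14600.5 in the dark, at least 3808-fold lower against a floor of 3 reads in that library, while its total mRNA was 51.0 RPKM in the dark and 68.4 in the light. Reads of GER1, F3H, SNRK2.5, MSRB7, UBQ6 and LHCB1.1 in the polysomal libraries were not whole numbers, as reads shared between genes would give, and GER1, F3H and SNRK2.5 also overlap another gene.

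By list, all 20 antenna genes (median 3.13) and all 26 photosystem subunits (2.29) rose in polysomal mRNA too. The Calvin cycle had 13 of 16 genes that rose (2.26), FBA1 by 3.13, flavonoid synthesis 11 of 16 (2.46), light regulators 17 of 21 (2.07) with BBX20 and BBX21 lower (-1.62 and -1.90), and chlorophyll synthesis 16 of 25 (1.33) with PORA and PORB (-2.26) lower. Of 11 carotenoid genes 6 rose, PSY by 2.56 and ZEP by 2.27. The stress list held 6 genes that rose, HSP70 by 2.07 and HSFA2 by 1.66, and 2 that fell, TCH3 (-1.46) and WRKY40 (-1.15). ELF4 (2.60), LNK1 (2.25) and PRR9 (1.49) rose in the clock list. Of 20 genes of etiolated growth and auxin 19 fell, to -4.76 in IAA6 and -4.60 in the cell wall enzyme gene XTH15, and HFR1 stood at -0.46. PHYA (-2.37), FHL (-2.46), FHY1 (-1.83) and PHOT1 (-1.14) fell, and PIF5 (1.35) and PIF4 (1.05) rose. Lower too were GRP7 (-2.04) and GRP8 (-1.17), PCK1 (-3.40), ICL (-2.32), ACX1 (-1.27) and ACX2 (-1.25), the seed storage genes CRC (-1.84) and CRA1 (-1.44), and SR34b (-1.07). The ribosomal protein gene RPL9D rose (1.45), with the other 30 between.

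In polysomal mRNA 1654 genes rose and 1817 fell, 47.7% of the changed genes higher, with a median of -0.17. Centring the ratios on the median of genes with at least 5 RPKM, a shift of -0.22, turned this to 2201 higher and 1213 lower (64.5% higher), so the balance of the 2 directions depends on the scaling. Among random lists, the ribosomal proteins lay at percentile 98.7, seed storage at 0.55 and storage oil breakdown at 2.08, the last within the random range at 8.61 once lists were also matched on gene length. Seed storage was no longer outside the range with a pseudocount of 5 (median -0.37), and too few of its members had at least 5 RPKM for a percentile (-1.44). Plastid-encoded genes (median -0.02, percentile 81.3), mitochondria-encoded genes (-0.31, 15.1), SR proteins (-0.02, 87.3), NMD factors (-0.41, 30.9), photoreceptors (-0.37, 25.2) and other splicing regulators (-0.55, 11.4) stayed inside it, and the 2 root markers had a median of -0.27. The lists of photosynthesis, pigments, light regulators, stress and clock lay above it and etiolated growth below.

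Light ratios in the 2 fractions were set side by side gene by gene. Of the 1888 genes that rose in total mRNA, 1340 (71.0%) rose in polysomal mRNA, against 177 expected from independent lists, and of the 1014 that fell 844 (83.2%) fell there, against 104. Another 965 genes fell in polysomal mRNA while lying between in total mRNA, and 313 rose there only by this rule, which does not test that the fractions differ. Only 8 genes rose in total and fell in polysomal mRNA and 1 did the reverse. Across genes Pearson's r was 0.87 and Spearman's rho 0.85, with genes not being independent replicates.

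Polysomal was compared with total mRNA in the dark to see which transcripts are rich or poor on polysomes. Among genes with a symbol and a mean of at least 10 RPKM the highest ratio was that of AGP13 (AT4G26320; chromosome 4, 13317053 to 13317640), an arabinogalactan peptide of the cell surface, at 97.0-fold higher in polysomal mRNA (77.4 to 123). RBCS1B (log2 5.78), AGP24 (4.90), OEP6 (4.41), PSAE1 (4.39) and RBCS3B (4.36) followed. The Rubisco small subunit genes together were 11.1-fold higher and LHCB1.1, LHCB1.2 and LHCB1.3 together 2.47-fold. At the low end of the same genes stood MIR156f (AT5G26147; chromosome 5, 9136106 to 9136237), a microRNA gene at 390.7 RPKM in total and 12.2 in polysomal mRNA, then TPX2 (AT1G65970, -3.87), ENODL1 (-3.35), HSD2 (-3.29) and EBP (-3.22). Photosystem subunits had 23 of 26 genes higher in polysomal mRNA (median 2.36; PSAK 3.54), the antenna 14 of 20 (1.44; LHCB1.2 3.53), the Calvin cycle 9 of 16 (1.48), ribosomal proteins 18 of 31 (RPL23AA 2.51, RPL8A 2.40) with RPL3B lower (-1.12), and etiolated growth and auxin 12 of 20 (1.26; SAUR21 3.41). CRC (2.56), CRA1 (2.16) and OLEO4 (1.44) of the seed storage genes were higher. Clock genes stood low, with 11 of 19 lower, PRR7 at -2.26 and LNK2 at -1.95, and ELF4 higher at 1.83. Of the NMD factors UPF3 (-1.60), BTZ1 (-1.49) and UPF2 (-1.22) were lower, and of 14 photoreceptors and PIFs 6, with PHYB at -1.78 and FHY3 at -1.73. The splicing factors U2AF65A (-1.86), U2AF65B (-1.55) and U2AF35B (-1.03) were lower while GRP8 (1.74) and GRP7 (1.18) were higher.

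In the light, within the same limit, MLP423 (4.19), AGP12 (3.90), AGP21 (3.86) and PSAE2 (3.83) stood highest. UBQ6 had 0 polysomal reads there, so its ratio of -6.10 is set by the pseudocount. Of the others MIR156f (-5.88), ASN1 (-4.20), a dark-induced asparagine synthetase, and EBP (-3.71) stood lowest. Photosystem subunits had 24 of 26 genes higher in polysomal mRNA (median 2.04), ribosomal proteins 22 of 31 (RPL28A 2.57), the antenna 15 of 20 (1.53), and flavonoid synthesis 6 (0.60; F3H 1.63, DFR 1.61) with PAL2 (-1.13) and C4H (-1.18) lower. The Calvin cycle had 5 of 16 higher (0.22), the 4 Rubisco small subunit genes and FBA1 (1.07). Lower were 12 of 19 clock genes (median -1.18; PRR7 -2.28), all 5 NMD factors (-1.55; BTZ1 -1.59, UPF1 -1.05), 7 of 14 photoreceptors and PIFs (-1.01; PHYB -1.92), 5 of 10 genes of storage oil breakdown (-1.06; PXA1 -2.78), 6 of 16 stress genes (-0.59; HSP90.1 -2.10), 22 of 68 plastid-encoded (-0.55) and 5 of 8 mitochondria-encoded genes (-1.12; ATMG01080 -2.52). The summed Rubisco small subunit genes were 6.42-fold higher in polysomal mRNA and the 3 LHCB1 genes 3.26-fold.

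Counts were 2916 genes higher and 2870 lower in the dark (50.4% of these higher, median -0.14) and 2258 and 3780 in the light (37.4%, median -0.31). Both depend on the scaling. Setting the sums over nuclear genes equal, a shift of 0.50 in the dark and 0.49 in the light, gave 1617 higher and 6177 lower (20.7%) in the dark and 1124 and 7324 (13.3%) in the light, and centring, a shift of -0.28 in the light, gave 3122 and 2263 (58.0%) there. Total and polysomal RNA were extracted by different methods, so the fraction and the extraction cannot be told apart in these values.

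Gene length went with the ratio. Genes of 0.5 to 1 kb had a median log2 ratio of 1.16 in the dark and 0.98 in the light, above that of genes of 3 to 5 kb by 2.16 in the dark and 2.22 in the light (2.17 to 2.28, bootstrap interval over genes). Across all genes Spearman's rho with length was -0.65 and -0.70. With the trend removed, a step that also centres the ratios on their median, 1358 genes were higher and 1237 lower in the light (52.3% higher). This balance is set in part by the centring. Random lists were therefore also matched on length, an alternative chosen after seeing the data. In the dark the photosystem (99.9), Calvin cycle (100), antenna (98.6), chlorophyll (99.9; median 0.48), light regulator (99.1; 0.57) and seed storage (99.1; 0.95) lists then lay above the random range and the clock (1.16) and plastid-encoded genes (0; -0.30) below. By expression alone, the Calvin cycle (78.1), antenna (83.8), chlorophyll (48.8), light regulator (91.8) and plastid-encoded (26.0) lists had lain inside the random range. Lists that had stood apart by expression alone and now lay inside it were etiolated growth (99.9 to 91.4), NMD factors (1.71 by expression alone), photoreceptors (0.47 to 33.1) and storage oil breakdown (1.29 to 36.9; median -0.69). Inside it by both measures were ribosomal proteins (94.1 and 70.9), flavonoid synthesis (83.2 and 91.5; median 0.15), stress (54.6 and 21.5; -0.02), mitochondria-encoded genes (25.5 and 25.1; median -0.20, mean 0.22) and other splicing regulators (7.88 and 8.43; -0.45), and so were SR proteins (median -0.17) and carotenoid genes (-0.21). In the light, NMD factors (0.695 to 11.7), photoreceptors (0.69 to 60.1), storage oil breakdown (0.60 to 29.1) and ribosomal proteins (99.7 to 96.9) came inside the range with matching on length. Stress genes (12.7 to 0.76), the antenna (97.3 to 100) and chlorophyll synthesis (28.7 to 98.3) came to lie outside it, with flavonoid synthesis at 100 and mitochondria-encoded genes at 0.08 after matching. Among members of at least 5 RPKM flavonoid synthesis (median 0.52, percentile 92.6) and plastid-encoded genes (-0.48, 27.8) lay inside the range in the light, and too few mitochondria-encoded genes were left for a percentile. Of the genes named for these ratios PSAE1, PSAE2, MIR156f, TPX2, ASN1, F3H, LNK2, U2AF35B and RPL3B overlap another gene, and the polysomal reads of the RBCS, LHCB1 and SAUR genes and of AGP21 were not whole numbers.

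**Figure D2:**
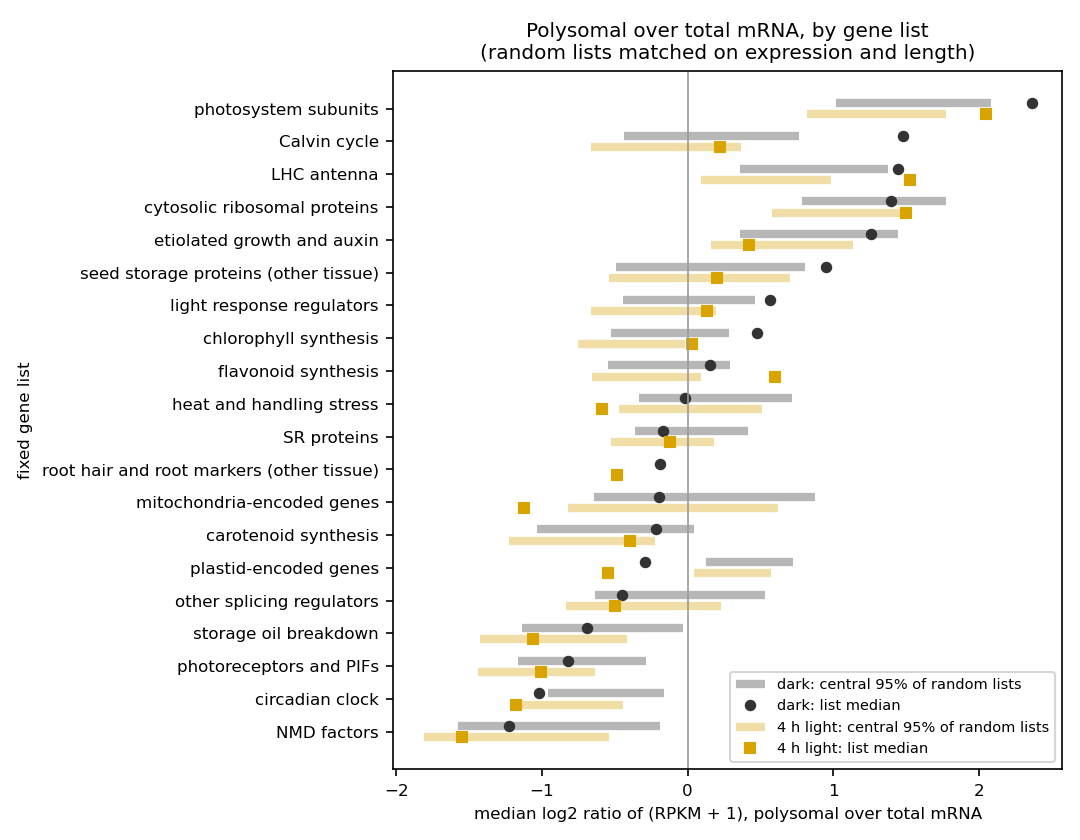
Median log2 ratio of (RPKM + 1), polysomal over total mRNA, for each gene list in the dark (circles) and after 4 h light (squares), with bars for the central 95% of random lists matched on expression and gene length. Photosystem subunits stand highest in both, at 2.36 and 2.04, and NMD factors lowest, at -1.22 and -1.55, the latter within their random range.

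**Figure D3:**
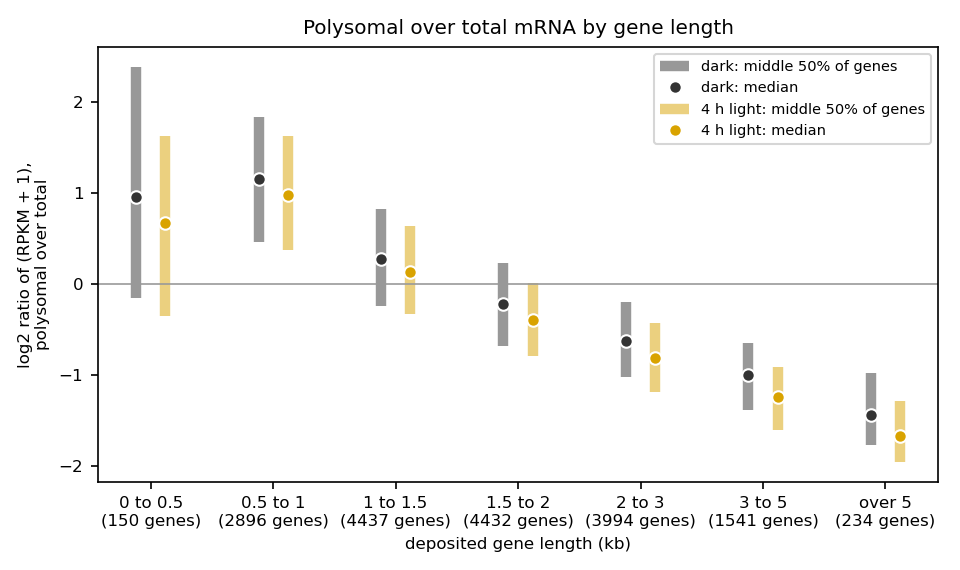
Log2 ratio of (RPKM + 1), polysomal over total mRNA, by deposited gene length in kb, in the dark and after 4 h light, with points for medians and bars for the middle 50% of genes. The medians of the 2896 genes of 0.5 to 1 kb, 1.16 and 0.98, lie above those of the 1541 genes of 3 to 5 kb by 2.16 and 2.22.

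The change of the polysomal over total ratio with light was the last comparison of expression. Among genes with a symbol and a mean of at least 10 RPKM the ratio rose most for GER1 (2.43), DR4 (2.02), the lipid transfer gene LP1 (1.72), TPX2 (1.71) and HSFA6A (1.69). Among list members below that limit the clock gene LHY (1.25) and GLK1 (1.38), a regulator of chloroplast genes, passed 2-fold, though not with a pseudocount of 5 (0.82 and 0.95). The anthocyanin genes DFR (1.44), LDOX (1.11) and F3H (1.02) passed 2-fold only through the 1 RPKM added to dark total values of 0.01, 0.02 and 0.16 RPKM, and without it their ratios of the fractions are lower in the light than in the dark. ESB1 (1.58) overlaps AT2G28671, whose polysomal reads were 11393 in the dark and 0 in the light. Within that limit AGP13 (-3.29), XTH18 (-2.85), MSRB7 (-2.80) and LHCB1.1 (-2.58) fell most after UBQ6, whose value of -8.44 is set by 0 light reads and the pseudocount. The reads of MSRB7 and LHCB1.1 were not whole, and summed over LHCB1.1, LHCB1.2 and LHCB1.3 the polysomal over total fold went the other way, from 2.47 in the dark to 3.26 in the light. Of the 91 genes whose ratio changed by 2 or more on the log2 scale 42.9% had polysomal reads that are not whole, and of the 29 at 3 or more 65.5%, against 22.5% of all tested genes. AT2G28671, without a symbol, went to -7.72, set by its 0 reads. In the Calvin cycle 6 of 16 genes fell, RBCS1B by 2.08, FBA1 by 1.97, and RCA (-1.67), SBPASE (-1.56), RBCS3B (-1.53) and PRK (-1.45) with them, and 10 lay between (median -0.85). The reads of RBCS1B and RBCS3B were not whole, and the 4 Rubisco small subunit genes summed went from 11.1-fold to 6.42-fold, a change under 2-fold. Of 20 genes of etiolated growth and auxin 8 fell, IAA6 to -2.07 and SAUR21 to -1.47 (median -0.77). Mitochondria-encoded genes had 5 of 8 lower (-1.47; ATMG00030 -2.86) and plastid-encoded genes 12 of 68 lower and 2 higher (-0.34). GER1, TPX2, F3H, RCA and PRK overlap another gene. No ribosomal protein (median 0.13) or SR protein (0.05) passed 2-fold.

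By this rule 131 genes rose and 578 fell (18.5% higher, median -0.18), and centring, a shift of -0.21, made this 267 and 333 (44.5% higher). The mitochondrial, plastid and etiolated growth lists lay at percentile 0, the Calvin cycle at 0.01, ribosomal proteins at 100, SR proteins at 99.9 and flavonoid synthesis at 99.8 (median 0.16). The flavonoid call was lost, and the median turned negative, with a pseudocount of 0.1 (-0.14) and among members of at least 5 RPKM (-0.27). Too few mitochondria-encoded genes had at least 5 RPKM for a percentile (median -1.56). The stress list, at 1.21 (median -0.43), lost its place at pseudocounts of 0.1 (-0.41) and 5 (-0.27) and among members of at least 5 RPKM (percentile 3.06). Inside the random range lay the antenna (-0.24), photosystem (-0.30), chlorophyll (-0.39), carotenoid (-0.20), clock (-0.14), light regulator (-0.30), NMD (-0.33), other splicing (-0.26), photoreceptor (-0.35), storage oil (-0.37) and seed storage (-0.44) lists, and SHR (-0.19) and SCR (-0.40) gave the root markers a median of -0.29.

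Splicing was surveyed in the authors' event tables, which list 22449 events in 9716 genes of total mRNA. Retained introns made up 61.7% of them (61.0 to 62.3, exact binomial interval), alternative donor or acceptor sites 34.4% (7723 events), cryptic exons 2.70% and exon skipping 1.22%. The polysomal table lists 7529 events in 4692 genes, 57.5% of them retained introns (56.4 to 58.6) and 37.2% alternative donor or acceptor sites (36.1 to 38.3).

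RS31, an SR protein, kept intron 2 (TAIR10.1 chromosome 3, 22901256 to 22902053, within the coding sequence) in 76.3% of reads in the dark (71.2 to 80.9) and 32.7% in the light (28.1 to 37.5), an adjusted p of 7.28e-29 by Fisher's exact test with Benjamini-Hochberg adjustment. GRP8 kept intron 1 (chromosome 4, 18274568 to 18274850) in 36.7% and 10.7% of reads, with a Fisher p of 7.18e-233 after Benjamini-Hochberg adjustment, and its relative GRP7 kept intron 1 (chromosome 2, 9265894 to 9266202) in 25.3% and 10.7%. Retention of SR30 intron 10 went from 77.8% to 59.9% and of RS41 intron 2 from 28.1% to 9.26%. All these introns bring a stop codon into the reading frame of the reference model. Of 51 tested events in SR genes 7 fell and 2 rose, the latter SR34 intron 10 (41.1% to 51.3%) and SR34b intron 10 in the 3' UTR (69.3% to 86.7%), and of 24 in the other splicing regulators 7 fell and none rose, among them introns of U2AF65A (83.1% to 72.8%), U2AF65B (96.4% to 84.5%) and U1-70K, which fell by 10.4 points to 44.6%. Alternative sites of SR30 (76.7% to 53.2%) and RS31 (85.1% to 49.8%) fell as well. Each lies within an intron named above as retained, as do changed sites of U2AF65A and U2AF65B, so these pairs are not independent events. Use of such a site keeps only part of the intron, and its reads can count as reads of the intron. The intron shares given for these genes need not be retention of the whole intron.

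In the clock list 3 of 53 events fell and 1 rose. LHY retained an intron of its 5' UTR in 31.6% of dark and 4.35% of light reads, from 79 and 69 reads, RVE8 had one intron lower (22.8% to 10.2%) and one alternative site higher (11.4% to 27.2%), and an alternative site of LNK2 fell (25.6% to 12.7%). Among the light regulators an alternative site of SPA1 fell (25.5% to 0.66%) and so did intron 1 of HYH (66.7% to 32.3%, from only 18 reads in the dark), while intron 3 of BBX22 rose (15.4% to 38.6%). The chlorophyll genes had 6 events lower and 3 higher of 26, all in 3 of the 11 genes tested. CHLM, a methyltransferase of chlorophyll synthesis, went from 4.55% to 31.4% at intron 2, in the 3' UTR of the model (Fisher, Benjamini-Hochberg adjusted p = 4.79e-83). MPK17, a MAP kinase gene, went from 63.1% to 36.9% at intron 5 (adjusted p = 1.88e-118, Fisher with Benjamini-Hochberg) and an alternative site of DIN10 from 34.5% to 19.1%. The largest shifts were of AT2G32650, where an intron of the 5' UTR went from 2.16% to 95.7% of reads, of ORP2B intron 1 from 1.75% to 91.3%, from 57 and 23 reads, and of AT5G61530, where an intron fell by 85.0 points to 4.98%, the dark value from 20 reads. Next came NPQ1, an enzyme of the xanthophyll cycle, from 8.74% to 90.9% at intron 1, and an alternative site of AT3G02300 from 83.5% to 1.41%. NPQ1 and CHLM overlap another gene, so part of those intron reads can belong to the partner. Read numbers given for introns may count spliced reads more than once, so the true numbers can be lower.

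**Figure D4:**
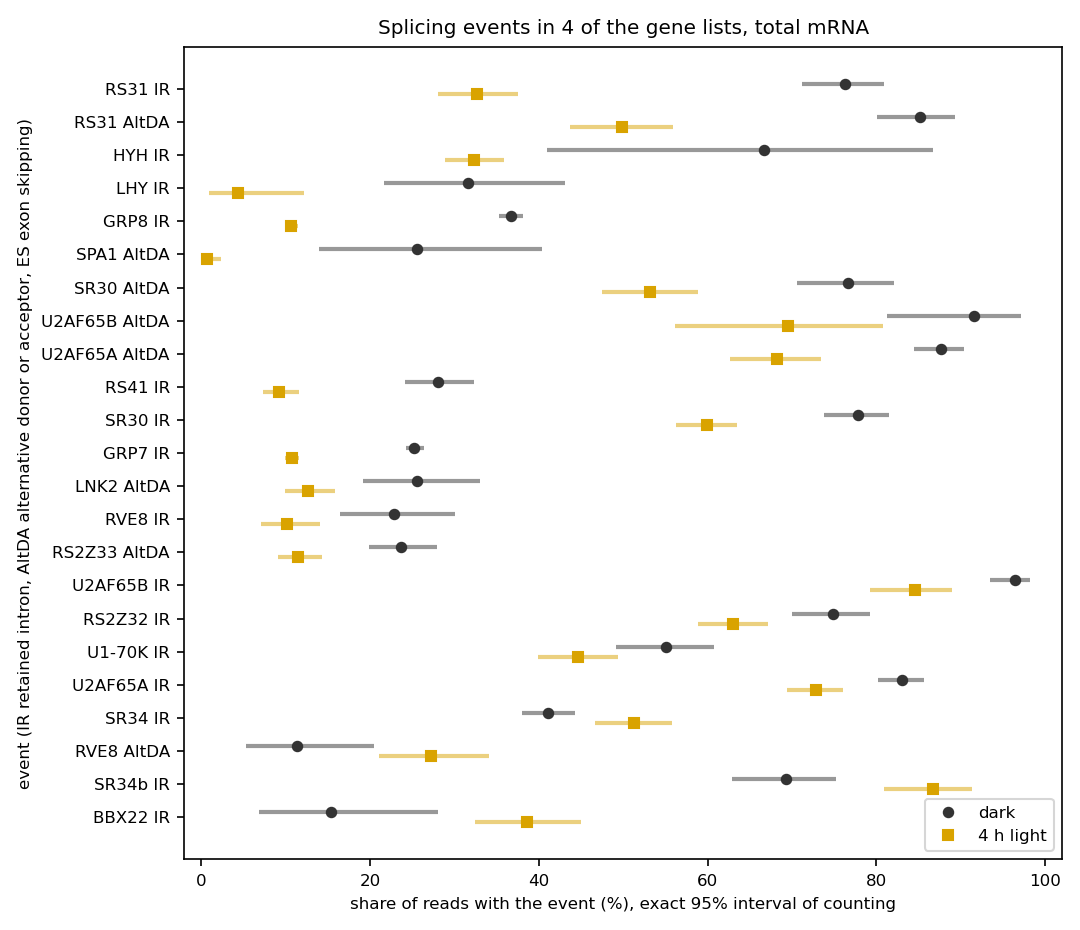
Share of reads with each splicing event in the dark (circles) and after 4 h light (squares), total mRNA, for the events past the rule in SR proteins, other splicing regulators, clock genes and light response regulators, with exact 95% binomial intervals of counting. Most shares are lower in the light, as in RS31 (76.3% to 32.7%) and GRP8 (36.7% to 10.7%), and a few are higher, as in BBX22 (15.4% to 38.6%). Intervals of retained introns may be too narrow, as their spliced reads may be counted more than once.

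Of 20007 tested events, 820 fell and 513 rose by at least 10 percentage points at an adjusted p of 0.05 or less, in 1094 genes, so that 61.5% of the changed events were lower in the light (58.8 to 64.1). Over all tested events, changed or not, the median change was 0.22 points, with 0.43 for retained introns and -0.23 for alternative donor or acceptor sites, so the balance of the changed retained introns was not that of all of them. Retained introns gave 573 lower and 391 higher of 12613, alternative donor or acceptor sites 238 and 115 of 7147, and exon skipping 9 and 7 of 247. In other lists both changed events of the Calvin cycle were lower, of 5 tested, and 1 of 6 in storage oil breakdown, while 1 event rose in each of the carotenoid, photoreceptor, ribosomal and etiolated growth lists, of 20, 45, 5 and 16 tested. No event passed in the NMD factors (0 of 11), antenna (0 of 3), flavonoid (0 of 4), stress (0 of 3), photosystem (0 of 1) or seed storage (0 of 1) lists. Fisher's test on reads compares these 2 libraries, not the conditions. Spliced reads of retained introns may be counted more than once, so their p-values and intervals may overstate the evidence. The authors' deposited table of light-regulated events holds 3809 events, of which 3429 were tested here and 2182 (63.6%) had an adjusted p of 0.05 or less by Fisher's test with Benjamini-Hochberg adjustment, 1196 of them with a change of at least 10 points.

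In polysomal mRNA, RS31 intron 2 was at 59.0% in the dark and 12.3% in the light, SR30 intron 10 at 44.2% and 11.1%, GRP7 intron 1 at 10.3% and 3.68% and GRP8 intron 1 at 7.55% and 2.29%. CHLM intron 2 was at 11.9% and 28.3%. Other named events went the opposite way to total mRNA, the alternative sites of AT3G02300 (22.2% to 38.5%) and DIN10 (37.4% to 40.9%) and introns of SR34 (10.6% to 7.69%), HYH (7.69% to 9.63%) and U1-70K (32.4% to 34.4%). Of 666 changed events with polysomal values 483 moved the same way there (72.5%, 69.0 to 75.9, an interval that takes events as independent). This held for 76.9% of the events lower in total mRNA and 65.5% of the higher ones. Among retained introns the shares were 78.9% and 62.2%, where 62.8% of all listed introns fell in polysomal mRNA with light. The median polysomal minus total difference of retained introns was -1.80 points in the dark and -5.17 in the light, where 72.9% of 4330 introns had the lower share in polysomal mRNA, against 57.4% in the dark. With light 62.8% of these introns had a lower share in polysomal mRNA and 45.2% in total mRNA. Alternative donor or acceptor sites differed by a median of 0.62 and 0 points. The read depth behind the polysomal shares is unknown, so they have no interval.

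Whether splicing and expression changed in common genes was asked over 9192 genes with an event. Of 1082 genes with a changed event 212 also rose or fell in total mRNA, an odds ratio of 1.49 and percentile 100 among random genes matched on expression. By direction, genes that rose shared 156 (odds ratio 1.61) and those that fell 56 (odds ratio 1.13, percentile 79.2). In polysomal mRNA 216 genes were shared (odds ratio 1.26, percentile 99.7), with odds ratios of 1.48 for genes that rose and 0.997 (percentile 45.0) for genes that fell.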

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

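All tests of the length trend but that on whole reads, the test on matched donor and acceptor events and the test on polysomal reads that are not whole were chosen after the result was seen.

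Of the genes tested, 9 moved at least 2-fold in opposite directions with light in total and in polysomal mRNA, a difference that was not tested. The log2 change in polysomal mRNA minus that in total mRNA was -7.72 for AT2G28671, -4.86 for ATCG01310, -3.77 for ATCG01170, -3.27 for AT1G05135, -3.27 for the AT14A copy AT3G28300, -3.14 for bZIP44, -2.87 for ATMG00030 and -2.61 for AT1G18020. It was 4.44 for AT3G13700, the one that fell in total and rose in polysomal mRNA. For bZIP44, AT14A and ATCG01170 the dark value in total mRNA was listed with 1 read, as was the light value for AT3G13700. No gene is listed with 0 reads in total mRNA, so a count of 1 may stand for 0. AT2G28671 and ATCG01310 had 0 polysomal reads in the light and AT3G13700 in the dark, so the size of these differences is set by the pseudocount. ATMG00030 went from 42.7 to 121 RPKM in total and from 396 to 152 in polysomal mRNA.

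Data outside every comparison also held signal. Values for polysomal mRNA alone were listed for 509 genes, AT1G58983 at 152 RPKM in the dark and 72.6 in the light and the transcription factor bZIP1 at 108 and 52.2. No change is read from AT1G58983, since its 5024.67 light reads equal those of AT1G58684 and of AT1G59359, which had 0 in the dark against its 13463.3. Values for total mRNA alone were listed for 1048 genes, MIR156d at 16.9 and 5.71 RPKM and TPS-CIN, a terpene synthase gene, at 2.56 and 15.1. The table of total mRNA events also holds 607 cryptic exon events without a test.

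The first pattern weighed is the fall of the polysomal over total ratio with gene length. The gap between the medians of genes of 0.5 to 1 kb and of 3 to 5 kb stayed at 2.07 (2.02 to 2.13, bootstrap 95% interval) on the log2 scale in the dark with RPKM recomputed from reads and deposited lengths, which argues against the length used for the polysomal RPKM. Among genes with whole polysomal reads it was 2.15 (2.09 to 2.22), which argues against shared reads. In the light it was 2.22 (2.17 to 2.28) and in the dark 2.16, the like size that the different extraction of the 2 fractions could give and that a preference of polysomes for short mRNA would give as well. Since every polysomal library was extracted one way and every total library the other, these cannot be told apart.

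The second pattern is the lower share of retained introns in polysomal than in total mRNA in the light. Donor or acceptor events matched to 4323 retained introns on share and reads differed by a median of -0.75 points (-0.97 to -0.50), against -5.20 for the introns, which argues against the choice of events as the cause. Introns in untranslated regions, which lie outside the coding sequence, differed by -4.61 points (-6.17 to -3.51, 489 introns), a value that unspliced nuclear RNA in the total fraction may give. Coding introns that bring a stop codon or a frame shift differed by -5.10 points (3551 introns) and the 83 that bring neither by -8.57, and the latter minus the former was -3.47 points (-8.00 to 0.57), an interval that includes 0. An early stop codon was predicted to put the stop or frame shift group lower than the other, by a margin that this interval excludes. The 83 and the 3551 introns were not matched with each other on share in total mRNA. No conclusion on an early stop codon is drawn from this gap, so that cause stays undecided. Both groups lay low among random introns matched on share, the first at percentile 0 (random median -4.82) and the second at 1.60 (-5.37). The first group makes up most of the introns these were drawn from, so its percentile tells little.

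The third pattern is a set of 84 genes with at least 5 RPKM in 1 fraction and at most 3 reads, or no value, in the other. This was asked in the dark and in the light apart, so some of them have ample reads of both fractions in the other condition. UBQ6 in polysomal light is among them. Of the 57 with polysomal reads, 64.9% (51.1 to 77.1) had reads that are not whole, against 22.5% of all tested genes, so the sharing of reads between related genes is a candidate explanation. Of the 62 placed on the reference 37.1% (25.2 to 50.3) overlap another gene, against 29.7% of all tested genes, too close to decide whether overlapping genes took each other's reads. The rest of the 84 were not placed, so their overlap is unknown and this share may not stand for the whole set. Among them AT5G64341, AT5G64342 and AT5G64343 list the same reads as each other in every library. A biological change of these genes was not tested.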

How the results depend on the processing

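Removal of the length trend, lists matched on length, genes that overlap no other gene, genes with whole reads, recomputed RPKM, cryptic exons and the background of tested events were chosen after the results were seen. No paired test was run, as each group holds 1 library. Of 238 recomputed summary values 177 stayed the same (counts within 1.5 times, shares within their interval, odds ratios on the same side of the random range), and 61 did not. Of the medians of lists, 563 kept their place against the random range, 15 came to lie outside it and 20 inside it or without a percentile, where under 5 members were left. Reversed were 2, both of flavonoid synthesis in the change of the ratio: -0.14 at a pseudocount of 0.1 and -0.27 among members of at least 5 RPKM. Named events kept their call in 144 cases and lost it in 15, all of these at 20 points. At a minimum of 20 reads 36 named events were still tested. ROPGEF2, AT1G13410, AT2G32160, AT4G02620 and HYH had too few reads there and are in neither count. Of the ratios of genes named by the fixed rules 1732 stayed within their counting interval, 1253 moved beyond it and none past 2-fold changed sign. Ratios named outside these rules, such as the change of the polysomal over total ratio of F3H, were not recomputed. Polysomal reads that are not whole limit the polysomal ratios, and genes near 1 RPKM by depth.

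A pseudocount of 5, which by construction pulls ratios toward 0, gave 1231 genes higher and 536 lower in total mRNA with light, 1041 and 1007 in polysomal mRNA, 1344 lower in polysomal than total mRNA in the dark and 1729 in the light, and 62 and 300 for the change of the ratio, where a pseudocount of 0.1 gave 229 and 900. At 1.5-fold, a wider threshold, the counts were 3297 and 2666 in total, 2906 and 4257 in polysomal mRNA, 4446 and 5578 for polysomal over total in the dark, 3636 and 6730 in the light, and 560 and 2191 for the change. At 3-fold they were 950 and 305, 788 and 694, 1478 and 818, 1067 and 1116, and 34 and 140 in the same order. Genes that overlap no other gene, a smaller set, gave 1240 higher in total mRNA. A mean of at least 5 RPKM left 72 higher in the change.

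Centring gave 2263 lower in polysomal than total mRNA in the light, and 267 higher and 333 lower for the change. Rescaling to nuclear genes gave 1617 higher and 6177 lower in the dark and 1124 and 7324 in the light. Plastid genes held at most 0.325% and mitochondrial genes at most 0.108% of the listed reads of a library. That argues against the removal of organelle genes as the cause. The rescaling sets the summed RPKM of the libraries equal, and reads on shorter genes give a higher sum. Shorter genes had higher polysomal over total ratios (Spearman's rho with length -0.65 in the dark and -0.70 in the light), which goes with this shift. How much of the shift it gives was not tested, nor were other causes. With the length trend removed, which also centres the ratios and so acts on this balance, these were 1776 and 1530 in the dark and 1358 and 1237 in the light. Matching on length put 6 lists above and 2 below the random range for polysomal over total mRNA in the dark (3 and 4 without it), and members of at least 5 RPKM put 3 below it for the change (5 without it).

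With each gene counted once per type, retained introns made up 58.8% of events in total mRNA, donor or acceptor sites 36.4% and exon skipping 1.88%, and exon skipping 2.07% in polysomal mRNA. In genes of at least 5 RPKM retained introns made up 58.1%, donor or acceptor sites 37.5% and cryptic exons 3.06% in total mRNA, and 54.1% and 39.9% were retained introns and donor or acceptor sites in polysomal mRNA. The cause of these shifts was not tested. At 20 points 351 events fell and 229 rose with light, 237 and 171 of them retained introns and 109 and 55 donor or acceptor sites. Event minimums of 5 and 20 reads and the overlap with expression changed no summary beyond these limits.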

Other observations

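The test of microRNA genes was written before its result was seen. The families and classes below, 10 in all, were run after values of some members had been seen. Percentiles are among lists matched on expression and gene length, a setting also chosen after the data were seen, unless said otherwise.

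Arabinogalactan proteins, glycoproteins of the cell surface, were mostly higher in polysomal than in total mRNA. Of 25 AGP genes 21 were higher in polysomal than in total mRNA in the dark (median 2.22, percentile 99.6) and 19 in the light, with 1 lower (1.77, percentile 98.8). With light 4 fell and 1 rose in total mRNA (median -0.62, percentile 0) and 12 fell and 1 rose in polysomal mRNA (-0.81, percentile 0), AGP4 to -4.57, and the ratio of the fractions fell in 6 (median -0.49, percentile 1.61). Genes of the ROTUNDIFOLIA-like small proteins, regulators of organ shape, went down with light in 6 of 15 cases in total mRNA (median -0.72, percentile 0.01; RTFL13 -2.66) and in 8 in polysomal mRNA (-1.14, percentile 0.01; RTFL13 -4.76), 1 rising in each, and had a median polysomal over total ratio of 1.37 in the dark (percentile 95.7, and 100 matched on expression alone) and 0.41 in the light (9.10, and 99.4 on expression alone). The ratio fell in 6 and rose in none (median -0.57, percentile 1.16, and 0.01 on expression alone). Xyloglucan hydrolases, which remodel the cell wall, went both ways: of 20 XTH genes 6 rose and 7 fell in total mRNA (median -0.09, mean 0.28), with XTH7 at 5.32, XTH6 at 3.63 and XTH15 at -3.31, and 6 rose and 9 fell in polysomal mRNA (-0.77, percentile 0.13), with XTH7 at 3.98, XTH6 at 3.00, XTH15 at -4.60 and XTH18 at -2.70 against 0.15 in total mRNA. Their median ratio of the fractions was 0.45 in the dark (percentile 56.1) and -0.34 in the light (0.53, and 11.5 on expression alone), and it fell in 8 genes and rose in none (median -0.73, percentile 0). Of 14 expansin genes 3 rose and 5 fell in total mRNA (median 0.12, mean -0.32, percentile 74.7) and 2 rose and 4 fell in polysomal mRNA (-0.37, percentile 14.5). Of 8 MSRB genes, methionine sulfoxide reductases, 4 rose and 2 fell in total mRNA (median 0.68, percentile 94.7), and the median polysomal over total ratio was 1.90 in the dark (percentile 98.0) and 0.87 in the light (44.6). The 4 LTP genes had medians of 2.80 and 2.55 for that ratio, with no percentile.

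MIR156f had the lowest polysomal over total ratio among the named genes in the dark, and the hypothesis tested was that microRNA precursors, which are not translated, carry few ribosomes. Over 27 microRNA genes the median ratio was -0.72 in the dark and -0.93 in the light, percentile 0 in both, with 9 lower and 2 higher in the dark and 12 lower in the light (MIR822 at -1.83). The median lay below the lower end of the central 95% of random lists, as the hypothesis predicted. The difference was -0.62 in the dark and -0.73 in the light. Different extraction of the fractions, or nuclear RNA in the total fraction, could give it as well, and the test cannot tell these apart. The value given for this test was changed from the percentile to the difference after the percentiles were seen. Small nucleolar RNA genes (20, medians -0.92 and -0.53, percentiles 0 and 0.01) and long non-coding RNA genes (75, -0.43 and -0.71, percentiles 0.09 and 0) also lay below the random range, and transcribed pseudogenes (55) had medians of -0.21 (percentile 16.5) and -0.46 (0.76). Matched on expression alone, small nucleolar RNA genes in the light (25.7), long non-coding RNA genes in the dark (4.49) and pseudogenes in the light (12.7) lay inside it, while microRNA genes stayed below it (0.21 and 0.01). With light the microRNA genes had medians of -0.25 in total mRNA (percentile 0.97) and -0.40 in polysomal mRNA (1.36), and the change of their ratio lay at percentile 67.8.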
